A study of Mus musculus with 9 samples.

How the data were processed

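RNA was measured by sequencing in 9 libraries of mouse embryonic stem (ES) cells, which are cultured cells able to form all tissues of the embryo. Per the labels, C57BL/6 ES cells grown on gelatine with LIF were sorted on a cytometer by the level of a GFP-Myc fusion or of EYFP. The labels do not say which reporter was used for which sample. They give 3 populations named by Myc level (High, Medium and Low), with replicates numbered 1 to 3 in each and described as biological. Reads were single-end and 61 nt long, per the labels' protocols.

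The submitters' processing notes name cutadapt, Picard, RSEM 1.17 and limma, with no role or order. The genome build, the annotation and the use of strand are not given in the sources used here. The authors deposited a table of 13499 genes with Ensembl identifiers and a signal per library, gene counts on a scale close to CPM. The deposited signal in each library was in 100% of cases a whole multiple of the value of a single read, within 0.001 read. Column totals ran from 953055 to 1026948. Whole reads recovered from these steps numbered 11114936 to 16755566 per library. 85 genes had no name and held 1.71% to 2.53% of the signal; they stayed in the tests. 10 names belonged to more than 1 identifier.

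Groups were taken from the labels. Tests used limma 3.58.1 in R 4.3.3 with a variance trend on log2(signal + pseudocount), with all 9 libraries sharing an estimate of the spread and population as the only term. The pseudocount was 1 CPM, taken on each library's own column total. Genes were tested if they reached 1 CPM on that total in at least 3 libraries, which kept all 13499 genes. A version with a constant pseudocount and filter of 1 was computed first, in departure from the design fixed before the data were examined. It is listed among the alternatives and gave 3831 genes for High against Low where the fixed design gave 3832. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes on the log2(signal + pseudocount) scale understate the change of low genes. Folds given as ratios are ratios of mean signal.

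Gene lists, the rule for named genes, the test and the alternatives, except those listed below as added, were set before the data were examined. 35 lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the 35 lists, and again with an estimated correlation and with fry. Named genes were those with the 10 highest and 10 lowest fold changes for High against Low, and 5 each way for the other comparisons; for the departure of Medium from the mean of High and Low, where none passed, the 3 with the smallest p are given. They had to pass the threshold, exceed the 25th percentile of mean level and show no overlap between the populations, and predicted genes and pseudogenes were passed over. Up to 3 members of each list past camera's threshold for High against Low, and a fixed set of pluripotency and Myc family genes, were added. T, Gata6 and Cdx2 of that set were not among the gene names in the authors' table, so lists that hold them were tested without them.

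Transcript length, chromosome and coordinates came from GENCODE release M21 on GRCm38, matched by identifier for 13412 genes (99.36%); coordinates are on that build. The longest transcript stood for each gene. The labels share replicate numbers across populations. For High and Low, the deviations of same-numbered libraries from their population means correlated at 0.53, 0.26 and 0.18. These numbers exceed the preset 0.1, so the pairs were treated as paired in a check with a replicate block. It gave 5239 genes for High against Low. Low replicate 2 with High replicate 3 (0.31) and Low replicate 3 with High replicate 2 (0.12) also exceeded 0.1. The rule therefore does not single out the numbered pairs and is no evidence for pairing. Counts and p-values given below without mention of the block come from the fit without it. For High and Medium (0.35, 0.17 and -0.04) and for Medium and Low (0.24, 0.43 and -0.11) the rule was not met. The blocked counts had been printed together with these correlations, and the rule was then applied as written.

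Scripts were tested on simulated data. For High against Low over 13499 genes, limma recovered 23.9% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 95.5% of those changed 4-fold, with 13 of 134 calls unchanged genes. Alternatives covered the pseudocount, filter, normalization, variance model, sample weights, replicate block, leaving out libraries, and count models on recovered reads (edgeR 4.0.16 and DESeq2 1.42.0). Added after seeing the data were a transcript length correction with and without the block and with an estimated correlation, leaving out Low replicates 1 and 2 together, the constant pseudocount and filter, rescaling each library to the same total, and sample weights estimated gene by gene. Replicates differed by more than counting noise, which biological samples can do. The chi-square per degree of freedom ran from 2.37 for High replicates 2 and 3 to 56.99 for Low replicates 1 and 2, and was 25.75 for Low replicates 1 and 3 and 10.38 for Low replicates 2 and 3. On the first principal component, Low replicate 1 lay at -9.4, and Low replicates 2 and 3 at -51.3 and -36. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.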

Results

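The series measured RNA in mouse ES cells, to ask how the transcriptome differs with Myc level. The cells were sorted by a GFP-Myc fusion or EYFP into 3 populations named by Myc level. Myc is a transcription factor that promotes growth and ribosome production. There were 9 libraries, 3 each of High, Medium and Low, each sequenced to between 11114936 and 16755566 recovered reads. In the order of replicates 1 to 3, Low had 13545200, 11480782 and 12482552 reads, Medium 16755566, 11114936 and 15285397, and High 15319564, 11429949 and 12565346. Values are the authors' normalized read counts on a scale close to CPM, given as mean ± SD with n = 3.

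Myc RNA followed the sort in every library. It was 26 ± 1.75 (SD, n = 3) in Low, 67.1 ± 2.54 in Medium and 106 ± 5.71 in High. High exceeded Low 4.08-fold, Medium exceeded Low 2.58-fold and High exceeded Medium 1.59-fold. An exact two-sided permutation test of High against Low gave p = 0.1, the smallest value that 3 libraries against 3 allow. Because the labels name the sorted populations by Myc level, this checks the labels and is not a finding.

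**Figure D1:**
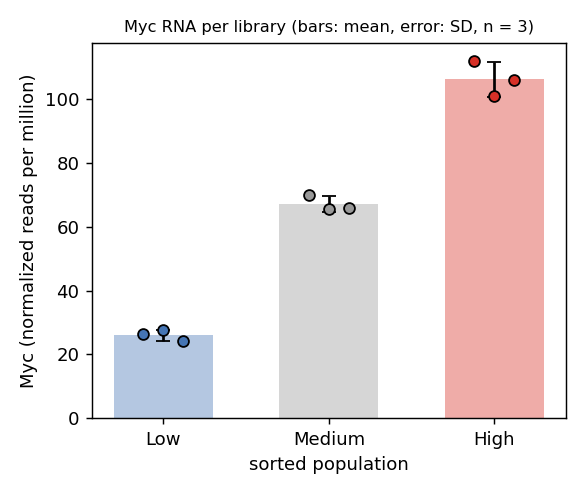
Myc RNA in normalized read counts (vertical axis) for each sorted population (horizontal axis); points are libraries, bars are means and error bars are SD with n = 3. The High libraries lie between 101 and 112 and the Low libraries between 24.2 and 27.6.

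This comparison asks which genes differ between the ends of the Myc range. Most naive pluripotency factors and most LIF and STAT3 targets were higher in High, and most trophoblast markers and p53 targets were lower. The netrin gene Ntn1 was 8.86-fold higher in High than in Low (34.7 ± 2.04 against 3.92 ± 0.402), and the transcription factors Gbx2 and Gli2 were 4.31-fold and 4.15-fold higher. The homeobox genes Rhox9 and Rhox6 were lower in High, at 9.56 ± 0.471 against 120 ± 18.7 and at 12.7 ± 1.38 against 128 ± 19.4. The imprinted non-coding RNA H19 was also lower, at 49.3 ± 3.48 in High against 303 ± 18.7 in Low. Of 13499 genes tested, 3832 (28.4%) changed between High and Low (limma, adjusted p under 0.05). Of these, 1866 were higher and 1966 lower in High. With each library rescaled to the same total, 1481 were higher and 2213 lower. Values are scaled per library, so higher and lower are relative to the other genes. Counts of list members below are to be read beside that 28.4%. The aminoacyl-tRNA synthetases and the immediate early genes come near it, though in each list all changed members moved in the same direction. A change of at least 2-fold on the log2 scale was seen for 312 higher and 363 lower genes.

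The other genes with the highest fold changes were Robo4, Ttn, Ankrd34a, Zfp423, Cobl and Myo1f, with log2 fold changes from 2.01 to 2.47. Robo4 is a receptor of the Roundabout family and Zfp423 a zinc finger transcription factor. Robo4 rose 7.16-fold from 2.66 ± 0.483 in Low. Ttn, which encodes the muscle protein titin on an annotated transcript of 106824 nt, rose from 7.13 ± 3.28 to 37.5 ± 8.43; its log2 fold change was 2.29, and 1.12 after a correction for transcript length. Among genes lower in High were Wnt7b, a Wnt ligand (2.67 ± 0.315 against 26.6 ± 3.12), and Krt7, an epithelial keratin (2.92 ± 0.257 against 19.7 ± 2.04). Lefty1, an inhibitor of Nodal signalling, fell from 355 ± 97.6 in Low to 60.7 ± 22.3 in High. Eps8l2, Klhl13, Dppa3 and the iron exporter Slc40a1 had log2 fold changes of -2.55, -2.27, -2.22 and -2.23. Rhox9 lies on chromosome X from 37899097 to 37901770, and Rhox6 from 37826910 to 37829857. They are members of a multigene family, so reads shared between copies may have been split by the authors' counting. H19 lies on chromosome 7 from 142575529 to 142578143, and Myc on chromosome 15 from 61985391 to 61990374.

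**Figure D2:**
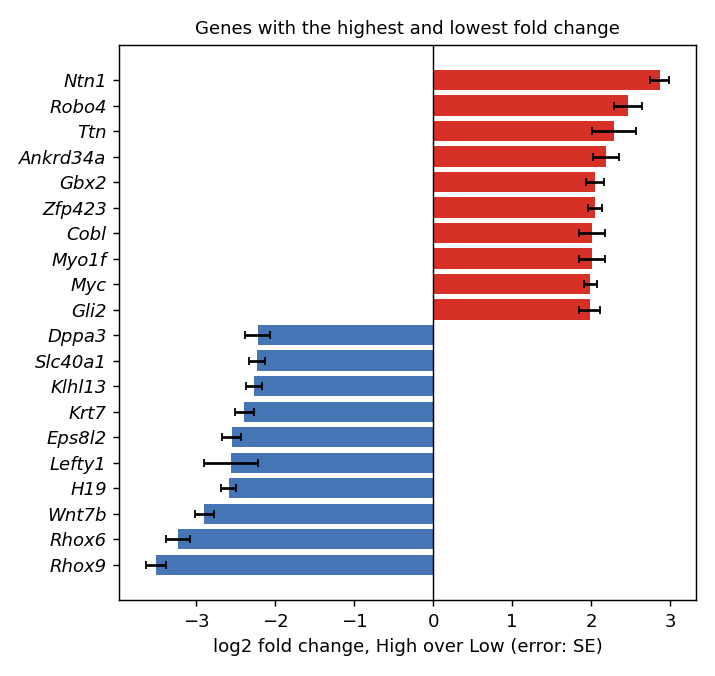
Log2 fold change of High over Low (horizontal axis) with its standard error for the 10 genes with the highest and the 10 with the lowest fold change under the naming rule (vertical axis). Values run from -3.51 for Rhox9 to 2.87 for Ntn1.

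Of 22 naive pluripotency factors, genes of the ground state of ES cells, 14 were higher in High, 4 were lower and 4 did not pass (camera adjusted p = 0.00342; adjusted p = 0.0794 with an estimated correlation). Adjusted over the list alone, 14 were higher and 6 lower. Gbx2 and Manba rose 4.31-fold and 2.38-fold, whereas Dppa3 fell by 2.22 on the log2 scale. Esrrb and Klf4 had log2 fold changes of 0.54 and 0.4, and the call for Klf4 was lost without High replicate 2 (adjusted p = 0.0688) or 3 (adjusted p = 0.0534). Nanog and Pou5f1 did not pass, with adjusted p = 0.132 and adjusted p = 0.0519; in the fit with the replicate block they passed, at 0.0338 and 0.00645, with log2 fold changes of -0.22 and 0.42, and Pou5f1 also passed after the transcript length correction, at 0.000271. Pou5f1 passed without Low replicate 2 (0.0418), Medium replicate 2 (0.0486) or High replicate 1 (0.0399). Sox2 did not pass, with adjusted p = 0.51. Fgf5 and Otx2, genes of the primed epiblast, were lower in High (log2 fold changes of -1.56 and -1.48), and Sox1, a neural gene, was higher (1.67). As a list, the primed epiblast markers had camera adjusted p = 0.957, with a median log2 fold change of 0.16 and a mean of -0.09.

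Of 17 LIF and STAT3 targets, 10 were higher, 1 was lower and 6 did not pass (camera adjusted p = 0.000285; adjusted p = 0.0573 with an estimated correlation; 11 and 2 adjusted over the list alone). Klf5 and Socs3 had log2 fold changes of 1.42 and 0.79. Gbx2, Klf4, Klf5 and Tfcp2l1 are in this list and in the naive pluripotency list, so these lists are not separate evidence. Of 16 FGF and ERK targets, 9 were higher and 1 lower (camera adjusted p = 0.00298; adjusted p = 0.0794 with an estimated correlation; 12 and 2 adjusted over the list alone). Etv4 rose 3.88-fold and Spry4 2.33-fold, and Ier3 fell by 1.5 on the log2 scale. Of 11 measured Wnt and beta-catenin targets, 5 were higher and 0 lower (camera adjusted p = 0.0306; adjusted p = 0.152 with an estimated correlation; 7 and 1 adjusted over the list alone). Notum, Bmp4 and Cdx1 had log2 fold changes of 1.96, 1.38 and 1.14; without Low replicate 1 the list gave adjusted p = 0.0648, and with the replicate block and a transcript length correction adjusted p = 0.0603.

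Primitive endoderm markers had 7 of 12 measured members higher and 1 lower (camera adjusted p = 0.00613; adjusted p = 0.147 with an estimated correlation; 8 and 1 adjusted over the list alone). Sparc and Hhex rose, by log2 fold changes of 0.95 and 1.05, and Dab2 fell by 1.13. Extracellular matrix and adhesion genes had 10 of 28 members higher and 1 lower (camera adjusted p = 0.00347; adjusted p = 0.638 with an estimated correlation; 11 and 1 adjusted over the list alone). Itga5 and Lama1 had log2 fold changes of 1.05 and 1.55; fry gave the list adjusted p = 0.051. Ribosome biogenesis and nucleolar genes had 40 of 92 members higher and 0 lower (camera adjusted p = 4.75e-08; adjusted p = 0.0794 with an estimated correlation; 48 and 0 adjusted over the list alone). Their median log2 fold change was 0.24; Nop2, Rrp1b and Ddx10 had 0.39, 0.64 and 0.46. Of 22 aminoacyl-tRNA synthetases, 6 were higher and 0 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.00494; adjusted p = 0.371 with an estimated correlation). Mars, Yars and Aars had log2 fold changes of 0.35, 0.28 and 0.33. The call for Aars was lost without Low replicate 3 (0.0595) or without High replicate 1 (0.0534), 2 (0.0685) or 3 (0.0677), and that for the list with quantile normalization (adjusted p = 0.232).

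Trophoblast markers, genes of the placental lineage, were lower in High for 12 of 14 measured members and higher for 1, also adjusted over the list alone (camera adjusted p = 7.58e-08; adjusted p = 0.0573 with an estimated correlation). Their median log2 fold change was -1.2, and Rhox9, Rhox6 and Krt7 led the list. Of 24 p53 targets, 16 were lower and 3 higher (camera adjusted p = 5.03e-07; 3 higher and 19 lower adjusted over the list alone). This was the 1 list of 35 that also passed with an estimated correlation without the length correction, at adjusted p = 0.0316. Ccng1, Perp and Ddit4, which are regulated in the response to stress, had log2 fold changes of -1, -1.81 and -2.04. RNA for p53 itself (Trp53) did not pass, with adjusted p = 0.817.

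Lysosome and autophagy genes had 13 of 35 members lower and 1 higher (camera adjusted p = 0.000201; adjusted p = 0.371 with an estimated correlation; 14 lower and 1 higher adjusted over the list alone). Psap and Grn had log2 fold changes of -0.66 and -0.6, and Tfeb, a transcription factor for lysosomal genes, rose 1.6-fold. Of 25 imprinted genes, 10 were lower and 0 higher (camera adjusted p = 0.0132; adjusted p = 0.0976 with an estimated correlation; 10 lower and 1 higher adjusted over the list alone). Sgce and Ascl2 had log2 fold changes of -1.48 and -1.67. Of 18 immediate early genes, 5 were lower and 0 higher (camera adjusted p = 0.0403; adjusted p = 0.567 with an estimated correlation; 6 lower adjusted over the list alone). Btg2, Jun and Klf6 were 2.52-fold, 2.06-fold and 1.48-fold lower in High. Btg2 is also in the list of p53 targets, and Ascl2 also in that of trophoblast markers. The list's call was lost without Low replicate 2 (0.0578), without High replicate 1 (0.125), with quantile normalization (0.0603) and with the transcript length correction (0.124). Of 33 replication-dependent histone genes only 3 were measured, of which Hist1h2bc and Hist1h4i were lower (camera adjusted p = 0.0306; adjusted p = 0.378 with an estimated correlation; 3 lower adjusted over the list alone). Hist1h1c gave adjusted p = 0.0525, and passed with the replicate block (0.00333) and after the length correction (0.0272), and without Low replicate 1 (0.0152) or Medium replicate 1 (0.0278) or 2 (0.0422). The call for Hist1h4i was lost without High replicate 1 (0.0518), and that for the list with quantile normalization (0.0603).

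Of 78 cytoplasmic ribosomal protein genes, 0 passed, although the list moved lower as a set (camera adjusted p = 0.00758; adjusted p = 0.993 with an estimated correlation). Their median log2 fold change was -0.2; Rpl10 and Rps28 had -0.51 and -0.42, and Rps28 passed with the replicate block, at 0.0365. Without Low replicate 1 Rpl10 and Rps28 passed, at 0.000585 and 0.00234. The list's call was lost without Low replicate 2 (0.776), without High replicate 1 (0.22) and with fry (0.548). Transcript length moved with this list: its median transcript was 1077 nt, against 3288 nt over all genes. After the length correction the list's median was -0.11 and 3 members passed as lower. The list still passed (camera adjusted p = 0.0162), but not with an estimated correlation (adjusted p = 0.886). Genes with transcripts of at least 5179 nt had a median log2 fold change of 0.16, and those of at most 1864 nt had -0.09. The trend differed among Low libraries, with a log2 difference between these long and short groups of 0.3 in replicate 1, -0.66 in replicate 2 and -0.3 in replicate 3. The extracellular matrix list had a median transcript of 5889 nt and the primitive endoderm list of 6117 nt. The ribosomal protein list moved in opposite directions in the 2 steps. Its median was 0.09 for High against Medium (camera adjusted p = 0.0472) and -0.3 for Medium against Low (3.58e-06). With an estimated correlation neither passed (adjusted p = 0.849 and 0.736). So it did not fall steadily with Myc level. In these steps fold change correlated with transcript length at -0.26 and 0.38 (Spearman).

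**Figure D3:**
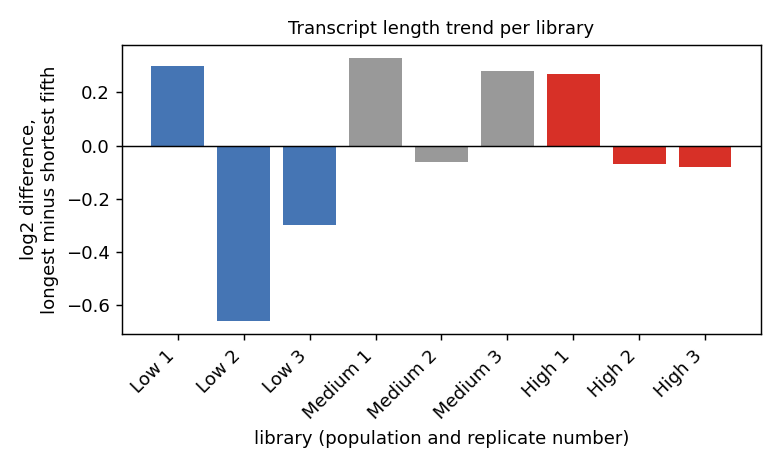
Median log2 deviation from the mean of all libraries for genes with transcripts of at least 5179 nt, minus that for at most 1864 nt (vertical axis) for each library (horizontal axis, population and replicate number). Low replicate 2 lies at -0.66 and Medium replicate 1 at 0.33.

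The Myc network list did not pass camera (adjusted p = 0.114) and passed fry (adjusted p = 1.08e-05), which does not compare a list with other genes; Mycn was lower in High (log2 fold change of -0.22), while Mycl and Max gave adjusted p = 0.105 and adjusted p = 0.186, and Max passed after the transcript length correction (log2 fold change of 0.24, adjusted p = 0.00731). Of 2 textbook Myc targets, Ncl rose (0.33, adjusted p = 0.0449) and Odc1 gave 0 (adjusted p = 0.986). The call for Ncl was lost after the transcript length correction (adjusted p = 0.365), and those for Ncl and Mycn without Low replicate 2 or 3, Medium replicate 2 or 3, or any High replicate, with adjusted p from 0.0644 to 0.127 for Ncl and from 0.0583 to 0.147 for Mycn. The lists with no call had these camera adjusted p values: general pluripotency 0.0781, primitive streak 0.403, neuroectoderm 0.882, fibroblast and feeder cells 0.946, and 2-cell-like state 0.838. Only 5 of 23 primitive streak, 10 of 21 neuroectoderm and 2 of 23 2-cell-like markers were measured. Tests of these lists, by camera or fry, therefore say little about those states. Translation factors gave 0.472, mitochondrial ribosomal proteins 0.957, oxidative phosphorylation 0.423, mitochondrial genome transcripts 0.695, glycolysis 0.423 and nucleotide synthesis 0.341. DNA replication gave 0.957, G2 and mitosis 0.403, apoptosis 0.882, cholesterol synthesis 0.957, heat shock 0.957 (median 0.03 and mean -0.02), epithelial-mesenchymal transition 0.341 and germline 0.172. By fry, which called 18 lists in all, general pluripotency (0.00698), primitive streak (0.0113), epithelial-mesenchymal transition (0.000104) and germline (0.00577) passed as well. By camera, general pluripotency passed after the length correction (0.0157) and without Low replicate 2 (0.0398). With an estimated correlation that list gave adjusted p = 0.378, and 0.193 with the length correction as well. Mitochondrial ribosomal proteins and oxidative phosphorylation passed without Low replicate 1 (0.00601 and 4.41e-05), and the former, in the other direction, without Low replicate 2 (0.0417).

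**Figure D4:**
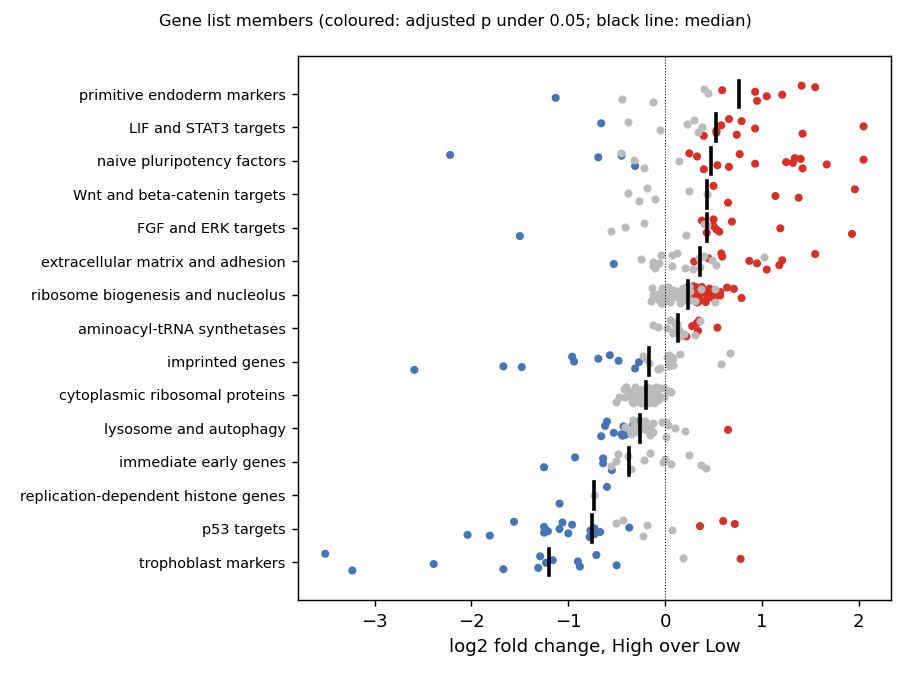
Log2 fold change of High over Low (horizontal axis) for each measured member of the 15 lists past camera's threshold (vertical axis). Coloured points passed limma's threshold, grey points did not, and black lines are list medians, from -1.2 for trophoblast markers to 0.76 for primitive endoderm markers.

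Of the 35 lists, 15 passed for High against Low with the preset correlation and 1 with an estimated correlation. After the length correction, p53 targets and trophoblast markers (adjusted p = 0.0205 each), LIF and STAT3 targets (0.0399), ribosome biogenesis (0.0467) and imprinted genes (0.0476) passed with an estimated correlation. Splitting the same 6 libraries in the 9 other ways gave 6 to 13 lists, so a camera call with the preset correlation is weak evidence for a list. The same 9 splits gave 0 genes each, against 3832. Each of them mixes High and Low libraries in a group, which adds any difference between them to the spread and by itself lowers the count. The number of genes ranged from 2345 without Low replicate 3 to 5846 without Low replicate 1, and was 2510 without High replicate 2. With the replicate block it was 5239.

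Between High and Medium few genes changed, and most of those were lower in High. Rhox9, Rhox6 and Wnt7b were again the most reduced, with log2 fold changes of -1.45, -1.44 and -1.4. Gbx2 was 1.85-fold higher in High, Ppm1j 1.71-fold and Etv4 1.65-fold. Of 13499 genes, 55 changed (limma), of which 11 were higher and 44 lower. Eps8l2 and Kif1a had log2 fold changes of -1.26 and -1.24, and Megf11 passed narrowly (log2 fold change of 0.75, adjusted p = 0.0489; 0.0514 after the length correction). Trophoblast markers (camera adjusted p = 3.43e-09; adjusted p = 0.0538 with an estimated correlation) had 4 of 14 members lower, and 6 adjusted over the list alone. p53 targets had 2 of 24 members lower, and 13 lower and 2 higher adjusted over the list alone, with camera adjusted p = 7.65e-08, and adjusted p = 0.0219 with an estimated correlation. 10 lists passed, with 1 passing with an estimated correlation and 2 with that and the length correction. Of the 10 named genes called, Rhox9, Rhox6, Wnt7b and Eps8l2 kept their call with each single library left out. The call for Myc itself was lost without any 1 of the Medium or High libraries, with adjusted p from 0.0513 to 0.0793. The count was 314 after the transcript length correction, 203 with the replicate block, 11 without Medium replicate 3, 12 without Medium replicate 2 or High replicate 1, 13 without Medium replicate 1 and 206 without Low replicate 1. It was 15 without High replicate 2, 16 without High replicate 3, 20 without Low replicate 3 and 92 without Low replicate 2.

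Between Medium and Low many more genes changed. Ntn1 was 5.63-fold higher in Medium, Gli2 3.21-fold and Cobl 3.14-fold. Rhox9, Rhox6 and Krt7 were lower, with log2 fold changes of -2.06, -1.79 and -1.56. H19 was 110 ± 11.3 in Medium and 303 ± 18.7 in Low. Of 13499 genes, 1621 changed (limma), of which 829 were higher and 792 lower in Medium; with each library rescaled to the same total, 608 were higher and 830 lower. Ttn and Ahnak, with annotated transcripts of 106824 nt and 18100 nt, had log2 fold changes of 1.9 and 1.49, and of 0.6 (adjusted p = 0.0464) and 0.89 after the transcript length correction. Wnt7b had -1.5. The call for Ahnak was lost without Low replicate 2 (0.0539) or 3 (0.0837) and without Medium replicate 1 (0.076) or 3 (0.0726). Naive pluripotency factors had 12 of 22 members higher and 2 lower (camera adjusted p = 0.000371; adjusted p = 0.0604 with an estimated correlation; 13 and 2 adjusted over the list alone). Trophoblast markers had 11 of 14 lower and 1 higher (camera adjusted p = 3.03e-07; adjusted p = 0.0604 with an estimated correlation; 12 and 2 adjusted over the list alone). p53 targets had 11 of 24 lower and 2 higher (camera adjusted p = 6.12e-06; adjusted p = 0.0552 with an estimated correlation; 13 and 3 adjusted over the list alone). 17 lists passed, 0 did so with an estimated correlation, and 6 with that and the length correction. Fold change rose with transcript length (Spearman 0.38 across genes, which are not independent replicates). The count was 2751 after the transcript length correction, 3656 with the replicate block, 5123 without Low replicate 1, 922 without Low replicate 2, 527 without Low replicate 3, 716, 889 and 573 without Medium replicates 1, 2 and 3, and 1063 and 1065 without High replicates 2 and 3.

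Across the 3 populations 2756 genes differed (limma's moderated F). The count was 5245 without Low replicate 1, 1395 without Low replicate 3, 1718 without High replicate 2, 1757 without High replicate 3 and 4496 with the replicate block. Medium lay between Low and High for 94.1% of the genes that changed between the ends. With Low at 0 and High at 1 on the log2 scale, the median position of Medium was 0.68 over those genes and 0.67 for Myc. Departure of Medium from the mean of High and Low was called for 0 genes by limma and by edgeR and 17 by DESeq2, with 766 genes at an unadjusted p under 0.05 by limma; without Low replicate 1 limma called 68. Ntn1, Sfrp1 and Enox1 had the smallest p, with adjusted p = 0.202, 0.23 and 0.599; after the transcript length correction Ntn1 (0.0398) and Sfrp1 (0.0286) passed. Fold changes of the 2 steps correlated across genes at 0.288 (Pearson) and 0.24 (Spearman). The Pearson value was 0.032 without Medium replicate 2, 0.14 without High replicate 1 and 0.173 without Low replicate 1. Both steps use the Medium libraries, which with no effect gives -0.503 in simulation. The covariance was 0.0244 against a simulated -0.0194, a difference of 0.0438. Both steps called 11 genes higher and 41 lower, and 0 in opposite directions. For independent lists 0.676 and 2.58 would be expected, but the 2 steps share the Medium libraries and an estimate of the spread, so these are not the counts that no effect gives.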

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

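Alternatives with the transcript length correction, without Low replicates 1 and 2 together, with a constant pseudocount and filter, with rescaling to the same total, and with gene by gene weights were chosen after seeing the data. For High against Low the log2 fold change of Myc stayed past the threshold under every alternative run, between 1.88 and 2.09; for High against Medium it lost its call in 9 of 32 settings and for Medium against Low in 1. Of 59 named genes called for High against Low, 54 kept their call with each single library left out and 42 under all 31 settings other than a 2-fold minimum; for High against Medium, 4 of 10 and 0, and for Medium against Low, 10 of 11 and 0. The filter alternative without a minimum removed no gene and tests nothing. The planned array weights stopped before they converged and gave Low replicate 3 a weight of 310, so Low was set nearly by that library alone; the resulting counts are not reliable. fry's p-values depend on the order of libraries; reversing it changed 0 calls.

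For High against Low the count was 3832, and moved to 9129 with array weights, 7850 with gene by gene weights, 6024 with the replicate block and length correction, and 675 with a 2-fold minimum. Leaving out libraries gave 702 to 5846. The replicate block gave 5239 and changed 4 named genes (Rps28, Hist1h1c, Nanog and Pou5f1) and no list count, which stayed 15. For High against Medium, 55 became 203 with the replicate block, 84 with no variance trend, 1080 with array weights, 801 gene by gene, 260 with DESeq2, 314 with length correction, 507 with the replicate block and length correction, 179 without Low replicates 1 and 2 together, 170 with only the 2 groups compared, and 13 with a 2-fold minimum. Leaving out libraries gave 0 to 206. For Medium against Low, 1621 became 3656 with the replicate block, 8784 with array weights, 7044 gene by gene, 2751 with length correction, 3822 with the block and length correction, 656 with only the 2 groups compared, and 176 with a 2-fold minimum. Leaving out libraries gave 1 to 5123. For the 3 populations, 2756 became 4496 with the replicate block, 10334 with array weights, 8344 gene by gene, and 5162 with the block and length correction; leaving out libraries gave 187 to 5245. Off the straight line, 0 became 1 with the replicate block, 3436 with array weights, 1153 gene by gene, 17 with DESeq2, 2 with length correction and 2 with both; leaving out libraries gave 0 to 68. The correlation of the 2 steps, 0.288, became 0.086 with array weights and 0.095 gene by gene, and 0.032 to 0.405 with libraries left out. The 15 lists became 1 with an estimated correlation, 5 with the length correction and an estimated correlation, and 13 to 16 with a library left out. The cause was not tested, except that a 2-fold minimum lowers counts by construction. The preset pairing rule was not met for High with Medium or Medium with Low, where replicate 3 gave -0.04 and -0.11. Replicates 1 and 2 lay above 0.1 there, so pairing is not ruled out. Of 9 libraries, 3 correlated best with their own number.

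Directions that reversed belonged to results with no call, except the mitochondrial ribosomal proteins for Medium against Low. Odc1 (0) became -0.02 with equal medians and array weights, -0.04 without Low replicates 1 and 2 together, -0.03 rescaled and -0.01 gene by gene; Sox2 became 0.01 with length correction, with and without the block. Leaving out libraries gave -0.06 to 0.05 for Odc1 and -0.11 to 0.02 for Trp53. Adjusted p of lists for High against Low that reversed were, with fry, primed epiblast 0.945, neuroectoderm 0.118 and heat shock 0.548, and with quantile normalization neuroectoderm and translation factors 0.976, nucleotide synthesis 0.945 and G2 and mitosis 0.817. With length correction they were primed epiblast and fibroblast 0.937, mitochondrial ribosomal proteins 0.23, oxidative phosphorylation 0.676, DNA replication 0.828 and cholesterol synthesis 0.953. With length correction and an estimated correlation they were primed epiblast, fibroblast, oxidative phosphorylation and cholesterol synthesis 0.986, and mitochondrial ribosomal proteins and DNA replication 0.931. With the block and length correction they were fibroblast and cholesterol synthesis 0.977, mitochondrial ribosomal proteins 0.246, oxidative phosphorylation 0.765, mitochondrial genome 0.949 and DNA replication 0.839. With libraries left out, adjusted p ran from 0.843 to 0.99 for primed epiblast, 0.567 to 0.96 for neuroectoderm, 0.408 to 0.97 for fibroblast, 0.131 to 0.775 for translation factors and 0.00601 to 0.993 for mitochondrial ribosomal proteins. It ran from 4.41e-05 to 0.924 for oxidative phosphorylation, 0.123 to 0.978 for the mitochondrial genome, 0.667 to 0.987 for DNA replication, 0.782 to 0.978 for cholesterol synthesis and 0.766 to 0.966 for heat shock. For Medium against Low it ran from 2.04e-07 to 0.937 for mitochondrial ribosomal proteins. Without Low replicate 2 the mitochondrial ribosomal proteins reversed to a call for High against Low (0.0417), and lost theirs for Medium against Low (0.937).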

Other observations

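The tests of transcript length, of the share of ES cells, of the spacing of Myc level and of splits within replicate numbers were chosen after the results were seen; the other split tests and the chromosome test were set beforehand.

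Genes of the Nodal and Hedgehog pathways beyond the named set were picked after their values were seen. Lefty2 was 25.2 ± 3.5 (SD, n = 3) in High and 93.4 ± 9.02 in Low (limma adjusted p = 1.71e-05). Nodal itself did not pass (adjusted p = 0.179), and the co-receptor gene Tdgf1 was higher in High (818 ± 40.3 against 502 ± 26.8, adjusted p = 0.000244). Of Hedgehog pathway genes, Gli2 was higher in High while Gli1 was lower (42.6 ± 1.54 against 55.9 ± 5.09, adjusted p = 0.0176), and Ptch1 did not pass (adjusted p = 0.552).

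The number of genes changed between High and Low was 3832. The other splits of those 6 libraries gave at most 0, including those that part all 3 numbered pairs. Such splits mix High and Low libraries in a group, which by itself lowers the count. For High against Medium the real split gave 55 and the highest other 1; for Medium against Low 1621 and 3; for lists 15 and 13. In each, 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05. Across all 9 libraries, 1 of 100 drawn splits gave as many genes as the real 2756, and the highest other gave 2606. Of the 36 splits with 1 library of each replicate number per group, 1 gave as many, the real one, and the highest other gave 1734. Chance was excluded in both only for a difference of some kind among the populations, at a share under 0.05. Each of these highest other splits kept the Low libraries together, which points to a structure in which Low stands apart. The split with 2606 genes set Medium replicate 2 and High replicates 2 and 3 against Medium replicates 1 and 3 and High replicate 1. Their log2 differences between long and short transcripts were -0.06, -0.07 and -0.08 against 0.33, 0.28 and 0.27. A division along the length trend thus gave nearly as many genes as that of Medium from High. Within replicate numbers, the other splits that did so gave 1734, 1650 and 1642, and the rest at most 1. Splits with Low kept together are too few to exclude chance for the division of Medium from High. For departure from the straight line the real count was 0, so all 100 drawn splits were as large, and the highest other gave 3314.

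A candidate explanation for the genes changed between High and Low is the transcript length trend between libraries. Against this, 98% of the 3832 genes were still called in the same direction after the length correction in the fit with the replicate block, and 96.6% without the block. For gain or loss of a chromosome in a population, tested with bounds set beforehand, the largest shift of a chromosome's median log2 fold change from that of all genes was -0.083 (SE 0.032) on chromosome X. It lies below 0.2 but not below 0.1 by more than its error, so small shifts stay open. The biological difference, Myc level, stays open and cannot be separated from other differences between the sorted cells.

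In High, 12 of 14 trophoblast markers and 16 of 24 p53 targets were lower than in Low, and 1 and 3 were higher; with an estimated correlation the trophoblast list gave adjusted p = 0.0573. The length trend may not account for them as a whole, since 94% or more of each list's median was left after the correction. A lower share of ES cells in Low would raise markers only of the other cell types present, so markers of a given lineage cannot rule out another. Primitive endoderm markers were higher in High, with a median log2 fold change of 0.76 (SE 0.29), and 0.47 after the length correction. Before it, 9 of 12 members were above 0. The list gave camera adjusted p = 0.147 with an estimated correlation, before and after. Several members, such as Sparc and Lama1, are also in the extracellular matrix list. Only 12 of 22 members were measured, with 7 called higher and 1 lower. The lower one was Dab2 (log2 fold change of -1.13, limma adjusted p = 0.000424). At most the list speaks, and weakly, against primitive endoderm cells as the type present. Trophoblast markers had medians of -1.2 (SE 0.39) and -1.13. Fibroblast and feeder cell markers, at 0.09 (SE 0.17) and -0.06, did not decide. A change in cells with trophoblast markers alone, or within the ES cells, stays open, as does Myc level itself.

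Fewer genes changed between High and Medium than between Medium and Low. After the length correction the first count was 11.4% of the second, against 3.4% before, so the length trend may contribute to the gap but does not remove it. With only the 2 groups compared, so that the third population adds nothing to the spread, the counts were 170 and 656, against 55 and 1621. Without Low replicate 1 they were 206 and 5123. The size of the gap therefore depends on the estimate of the spread, which the noisier Low libraries share. Uneven spacing of Myc on the log2 scale could account for the gap: Medium's median position over called genes differed from that of Myc by 0.01. That position was 0.72 for genes higher in High and 0.64 for those lower. In mean signal Myc was 26 in Low, 67.1 in Medium and 106 in High, steps of similar size on that scale. Medium's position over called genes also reflects the smaller fold changes between High and Medium themselves, so the match is not separate evidence. Uneven spacing is a hypothesis found and tested on the same data.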
